A study of Mus musculus with 8 samples.

How the data were processed

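Liver RNA of 8 mice labelled female was sequenced from total RNA with a stranded kit, 1 library per mouse, per the labels' protocols: 4 WT, 2 Ercc1 and 2 NemoDK_Ercc1. The deposited table holds raw counts per gene for these 8 libraries and 55487 gene identifiers. Per the submitters' processing notes FastQC, HISAT2 2.1.0 and featureCounts were used with the GRCm38 mouse genome. The notes give no annotation release, strand setting or handling of reads with several alignments, so values of paralogs and of genes whose exons overlap another gene are less certain. Of 96 genes named in the text, 8 have exons overlapping another gene on the same strand and 23 on the other strand.

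Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the data.table package (version 1.17.8), and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Genes with low counts were removed with filterByExpr on the 3 groups, which left 15598. TMM factors were computed, a quasi-likelihood model with 1 mean per group was fitted to all 8 libraries, and 3 contrasts were tested: Ercc1 against WT, NemoDK_Ercc1 against Ercc1, and NemoDK_Ercc1 against WT. Sharing 1 fit lets groups of 2 mice borrow the spread of the others (5 residual degrees of freedom, 3.67 prior degrees of freedom, common biological coefficient of variation 0.227). P values were adjusted by Benjamini-Hochberg over the tested genes with a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic.

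Gene lists for 35 processes and cell types were written, with the contrasts, the tests and most of the alternatives, before the data were examined. They were tested with camera at a preset correlation of 0.01, adjusted over the 34 lists with enough tested members. The list of pancreatic acinar markers had 2 tested members and was not tested. Some genes belong to several lists, so the list results are not independent of each other. Examples are Mmp12 (secretory genes and macrophage markers), Icam1 (NF-kB targets and secretory genes), Timp1 (extracellular matrix and secretory genes) and Cps1 (hepatocyte markers and gluconeogenesis). Camera with a correlation estimated per list, and fry, were the alternatives. An estimated correlation from 8 libraries is itself imprecise, and both values are given. Counts of list members are given over all genes and with p adjusted over the list alone.

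Genes named for a comparison followed a rule: Ercc1 and Ikbkg in every library; up to 10 higher and 10 lower genes with the largest fold change among those with adjusted p under 0.05, average log2 CPM of at least 1, every library of 1 group beyond every library of the other, and no predicted gene models; and up to 4 members per list with the smallest p. The list examples in the text are a choice from these, made after their values were seen, that favoured genes whose call held when any library was left out. Where a group had 0 counts the fold change is a lower bound that sets that group at 3 counts, and where it had 1 to 3 counts the ratio has a 95% counting interval.

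Alternatives were RLE, upper-quartile and no scaling factors, no filter or a filter at 1 CPM in 2 libraries, DESeq2, limma-voom, robust empirical Bayes, only the 2 groups compared, age as a covariate, other thresholds, and each library left out in turn. The share of the Ercc1 change found in NemoDK_Ercc1 was measured on genes chosen in 1 Ercc1 mouse and 2 WT mice (prior count 2) and followed in the remaining mice. Recovery was tested on simulated negative binomial counts with the mean CPM of each gene over all 8 libraries and the fitted spread. In each of 5 draws 200 genes above 1 CPM were changed and the NF-kB list was shifted 2-fold. The shifted list was found in 5 of 5 draws. Results of lists with few or no changed members were pooled over the draws, and 1 of 153 and 1 of 155 passed. Lists with a larger share of changed members were not counted. Genes were drawn independently of each other, so these shares cannot give the error rate of the list test where genes of a list are correlated.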

Results

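Liver RNA from 8 mice labelled female was compared across 3 genotype groups: WT (n = 4), Ercc1 (n = 2, ERCC1-deficient with 1 null and 1 hypomorphic allele) and NemoDK_Ercc1 (n = 2, the same Ercc1 genotype with a Nemo allele that the labels call DK without explaining the term). ERCC1 is an endonuclease subunit of nucleotide excision and crosslink repair, and NEMO, encoded by Ikbkg, is the regulatory subunit of the kinase that activates NF-kB. Each library came from a different mouse, and the labels paired no mice. The WT mice were 10.7, 12.3, 11.1 and 11.8 weeks old, the NemoDK_Ercc1 mice both 11.8 weeks, and the Ercc1 mice 15.1 and 13.7 weeks, older than every mouse of the other groups. Libraries held 23.2, 22.2, 24.6 and 27.8 M counts (WT 1 to 4), 24.8 and 26.9 M (Ercc1 1 and 2), and 27.7 and 21.6 M (NemoDK_Ercc1 1 and 2). Of 55487 genes, 15598 passed the filter on low counts and were tested. Fold changes are log2 values ± standard error from edgeR, and CPM are depth-normalized counts (scaled with TMM factors).

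The first principal component held 55.8% of the variance and separated the WT livers from both mutant groups, which lay together on it. The second held 16.8% and set WT library 3 apart from all other libraries. Correlations of log2 CPM were 0.957 to 0.983 among WT libraries, 0.979 between the Ercc1 libraries, 0.988 between the NemoDK_Ercc1 libraries, and 0.972 to 0.987 between Ercc1 and NemoDK_Ercc1 libraries, but 0.919 to 0.948 between WT and Ercc1. The share of counts from Malat1, Neat1, Meg3 and Kcnq1ot1 was higher in all 4 mutant libraries than in any WT library: 0.0341 to 0.0793% in WT, 0.120 and 0.0961% in Ercc1, and 0.130 and 0.0879% in NemoDK_Ercc1. Meg3 itself was 0.823 to 7.03 CPM in WT and 49.3 to 125 CPM in the mutant libraries. The separation may therefore rest on Meg3 and does not show a general shift of nuclear RNA. The share without Meg3 was not computed. WT library 3 held 0 Xist counts, against 9331 to 15744 in the other 7 libraries, and 3087 counts of 4 Y-linked genes, so its label of a female mouse did not match its RNA. It was kept, as planned, and values without it are given for the results it moved most.

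**Figure D1:**
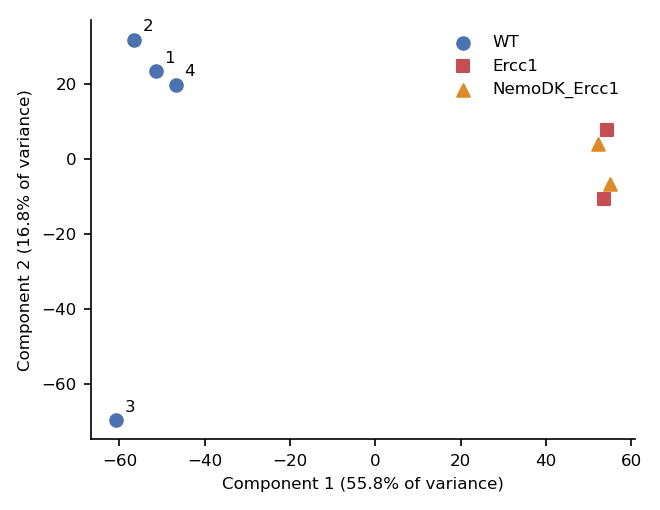
First and second principal components of log2 CPM over the tested genes, 1 point per library (n = 4 WT, 2 Ercc1 and 2 NemoDK_Ercc1 mice). WT libraries carry their replicate number.

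Ercc1 transcript was present at a low level in every library and lower in all 4 mutant livers than in any WT liver: 5.04, 2.57, 3.58 and 4.44 CPM in WT, 1.76 and 1.49 in Ercc1, and 1.87 and 1.86 in NemoDK_Ercc1. The fold change was -1.26 ± 0.30 in Ercc1 against WT (adjusted p = 0.0205) and -1.06 ± 0.30 in NemoDK_Ercc1 against WT (adjusted p = 0.0410), with 0.20 ± 0.34 between the mutant groups (adjusted p = 0.940). Without Ercc1 library 1 the first of these was -1.39 (adjusted p = 0.0870), and without Ercc1 library 2 it was -1.15 (adjusted p = 0.111). With age as a covariate it shrank to -0.65 (adjusted p = 0.702). The call in NemoDK_Ercc1 ended without WT library 1 (-0.92, adjusted p = 0.0799), WT library 4 (-0.996, 0.0853), Ercc1 library 1 (-1.07, 0.0532), Ercc1 library 2 (-1.07, 0.0530), NemoDK_Ercc1 library 1 (-1.07, 0.214) or NemoDK_Ercc1 library 2 (-1.06, 0.204). It also ended with upper-quartile factors (-0.97, 0.0589), library size alone (-0.80, 0.0810), a fit of only the 2 groups (-1.06, 0.0517) and age as a covariate (-0.98, 0.0659). Exons of Ercc1 overlap those of Cd3eap on the other strand, so some of these counts may belong to that gene if reads were not assigned by strand.

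Ikbkg transcript was not reduced in the mice carrying the Nemo allele: 56.8, 56.9, 68.4 and 63.4 CPM in WT, 93.3 and 84.0 in Ercc1, and 81.9 and 71.9 in NemoDK_Ercc1. It was higher in Ercc1 than in WT (0.53 ± 0.12, adjusted p = 0.0167), a call that ended without Ercc1 library 1 (0.45, adjusted p = 0.117) and with age as a covariate (0.46, 0.513). The change was 0.33 ± 0.12 in NemoDK_Ercc1 against WT (adjusted p = 0.0960, but called with upper-quartile factors, 0.42 and 0.0382, and with library size alone, 0.59 and 0.0135) and -0.20 ± 0.14 between the mutant groups (adjusted p = 0.817). Exons of Ikbkg overlap those of G6pdx on the other strand.

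**Figure D2:**
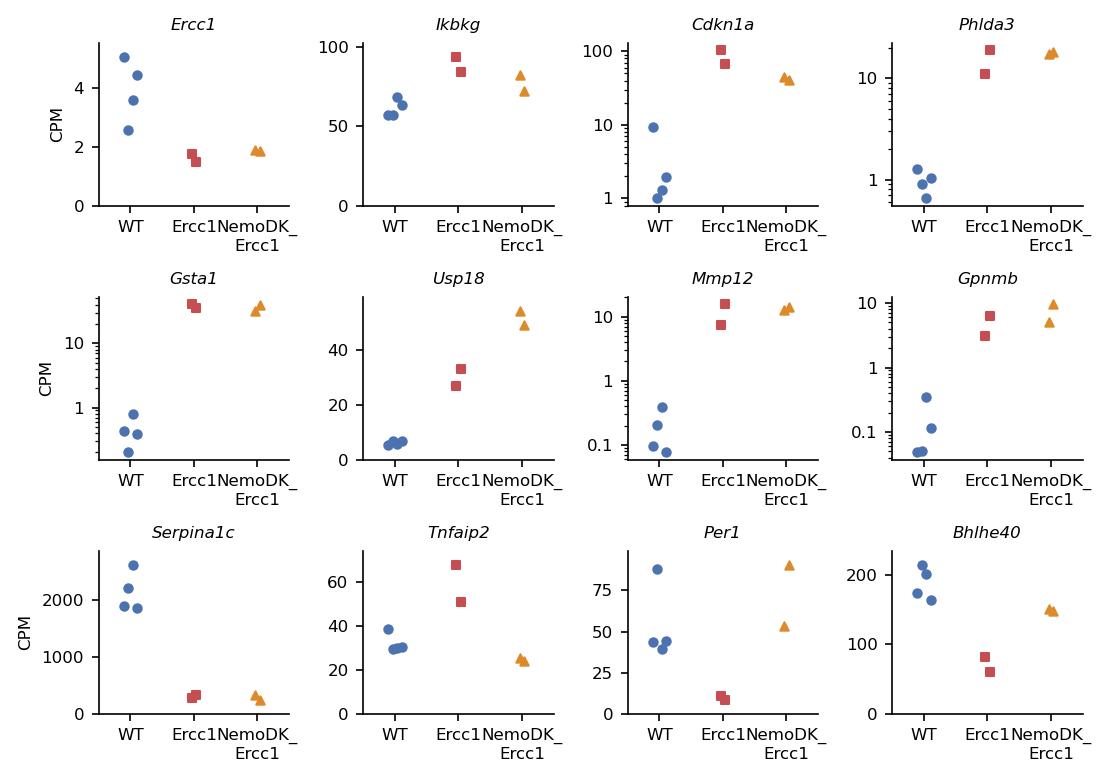
CPM of 12 genes in every library, for the genes of both alleles and for examples from the gene lists. Cdkn1a, Phlda3, Gsta1, Mmp12 and Gpnmb are drawn on log axes, the others on linear axes from 0.

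Livers of Ercc1 mice differed broadly from WT. Targets of p53, antioxidant genes controlled by NRF2, interferon-response genes, proliferation genes and markers of recruited macrophages were higher, and so were many secreted factors of senescent cells. Hepatocyte markers and genes of gluconeogenesis, fatty acid synthesis and the circadian clock were lower, though the clock list did not pass in NemoDK_Ercc1 against WT. The summed transcripts of major urinary proteins were lower. Most of the camera results behind this outline depend on a preset correlation between genes: of 17 lists that passed, 1 passed with an estimated correlation. Interferon-response, proliferation and fatty acid synthesis genes also did not pass with age as a covariate. With fry, the other alternative, 13 of 34 lists passed. Against WT, 1761 genes were higher and 1482 lower in Ercc1 (edgeR, adjusted p under 0.05), of which 1122 and 533 changed at least 2-fold. Without TMM factors the counts were 3765 higher and 690 lower, and the median log2 change of all tested genes was 0.26. With upper-quartile factors they were 2079 and 1141. Because the Ercc1 mice were the oldest, age was also added as a covariate, with which 24 genes were called higher and 17 lower, 38 of these 41 among the 3243 called without it. Over those 3243 genes the median change in the direction called went from 1.02 to 0.97, while the median standard error grew from 0.20 to 0.46, so most calls ended because the change could no longer be estimated well. Without Ercc1 library 1 the counts were 774 and 383, and without Ercc1 library 2 they were 1070 and 834.

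Of 34 p53 target genes tested, 17 were higher and 0 lower in Ercc1 livers (20 and 0 when adjusted over the list alone), with a median change of 0.82 (camera, adjusted p = 1.70e-12, but 0.192 with an estimated correlation). Cdkn1a, whose product p21 arrests the cell cycle, rose from 3.44 to 85.2 CPM (4.64 ± 0.71, adjusted p = 0.00362). Phlda3, which restrains Akt signaling, rose by 3.95 ± 0.27, Psrc1 by 5.70 ± 0.41, the death receptor gene Tnfrsf10b by 3.73 ± 0.40 and Plk2 by 1.498 ± 0.15. Among 26 NRF2 targets 16 were higher and 0 lower (18 and 0 over the list alone), with a median of 1.22 (adjusted p = 4.62e-16, and 0.0287 with an estimated correlation). No other list passed both ways, and the NRF2 list did not with an estimated correlation and age as a covariate (0.0812) or without WT library 2 (0.0713), WT library 3 (0.0811), WT library 4 (0.0660), Ercc1 library 2 (0.0588), NemoDK_Ercc1 library 1 (0.0656) or NemoDK_Ercc1 library 2 (0.0667). Its leading members were the glutathione transferase genes Gsta1 (6.38 ± 0.28) and Gsta2 (3.32 ± 0.29), Ugdh (2.09 ± 0.14) and the sulfiredoxin gene Srxn1 (1.92 ± 0.16). The 4 glutathione transferase alpha genes of the table summed to 1773 ± 327 CPM in WT (mean ± SD), 1644 ± 250 in Ercc1 and 1727 ± 83.0 in NemoDK_Ercc1. Gsta1 (41.1 and 36.1 CPM in Ercc1) and Gsta2 (146 and 101 CPM) are a small part of this sum. With its spread between mice, the sum therefore cannot show whether their rise changed the family total. Reads shared among these paralogs were not separated.

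Senescence-associated secretory genes were 14 higher and 3 lower of 41 (17 and 3 over the list alone), with a median of 0.77 (adjusted p = 9.72e-06, but 0.192 with an estimated correlation). Mmp12, a macrophage elastase that is also in the list of macrophage markers, rose by 5.88 ± 0.46. The urokinase receptor gene Plaur rose by 2.19 ± 0.31, while Vegfa fell by 1.01 ± 0.14. Lif, a cytokine gene with 2 counts in all WT libraries together and 107 in Ercc1, was 84.2-fold higher (95% counting interval 22.7 to 704). The median was unchanged with this gene and Ccl7 set to their bounds. NF-kB targets were 14 higher and 3 lower of 40 (18 and 3 over the list alone), with a median of 0.69 (adjusted p = 4.36e-04, but 0.219 with an estimated correlation). They included the receptors Tlr2 (1.78 ± 0.22) and Cd40 (2.53 ± 0.41), the adhesion molecule Icam1 (1.03 ± 0.17) and Cd83 (2.08 ± 0.35). With age as a covariate the NF-kB list no longer passed (adjusted p = 0.118). Of 6 cyclin-dependent kinase inhibitors 1 was higher (1 over the list alone), with a median of 0.35 (adjusted p = 0.282, and 0.466 with an estimated correlation). Without WT library 1, in which Cdkn1a was 9.49 CPM, that list passed (adjusted p = 0.00543, but 0.174 with an estimated correlation).

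Interferon-response genes were 25 higher and 0 lower of 41 (31 and 0 over the list alone), with a median of 0.99 (adjusted p = 1.58e-16, but 0.219 with an estimated correlation). Usp18, a brake on interferon signaling, rose by 2.28 ± 0.14, Xaf1 by 1.49 ± 0.12, and the antiviral genes Rsad2 and Oasl1 by 2.65 ± 0.23 and 2.39 ± 0.22. Proliferation genes were 24 higher and 0 lower of 38 (30 and 0 over the list alone), with a median of 1.77 (adjusted p = 3.28e-12, but 0.279 with an estimated correlation). E2f1 rose by 1.74 ± 0.21, and the mitotic genes Plk1 and Kif11 rose by 3.23 ± 0.45 and 1.68 ± 0.29, all from low levels. With age as a covariate neither list passed and both medians shrank. They were 0.41 for interferon-response genes (adjusted p = 0.0845) and 0.64 for proliferation genes (adjusted p = 0.0738).

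Monocyte and recruited macrophage markers were 10 higher and 0 lower of 13 (11 and 0 over the list alone), with a median of 1.67 (adjusted p = 1.13e-10, but 0.192 with an estimated correlation). They included Gpnmb (4.96 ± 0.58), Trem2 (2.83 ± 0.44), both expressed in lipid-handling macrophages, and Itgax (2.40 ± 0.33). Neutrophil markers were 3 higher of 6 (5 over the list alone), with a median of 1.35 (adjusted p = 0.00106, but 0.195 with an estimated correlation), S100a9 rising by 2.103 ± 0.34. Markers of B and plasma cells were 8 higher of 17 (12 over the list alone), with a median of 1.31 (adjusted p = 3.97e-04, but 0.466 with an estimated correlation). Ighg2c, an immunoglobulin heavy chain gene, rose by 2.56 ± 0.46. Without Ercc1 library 2 the B and plasma cell list did not pass and its median was 0.63. Extracellular matrix and stellate-cell genes were 10 higher and 1 lower of 29 (17 and 1 over the list alone). Their median was 0.70 (adjusted p = 6.85e-05, but 0.466 with an estimated correlation), and 0.27 without Ercc1 library 2, where the list did not pass. Examples were the collagen genes Col1a1 (2.58 ± 0.37) and Col4a1 (1.72 ± 0.25) and the protease inhibitor gene Timp1 (3.55 ± 0.58). Cholangiocyte markers were 4 higher of 10 (5 over the list alone), with a median of 0.92 (adjusted p = 0.0144, but 0.192 with an estimated correlation and 0.0502 with age as a covariate), Krt23 rising by 3.001 ± 0.44. Erythroid markers were 1 lower of 7 (5 over the list alone), with a median of -1.42 (adjusted p = 0.0308, but 0.466 with an estimated correlation). The erythroid call ended without WT library 1 (adjusted p = 0.0791), WT library 2 (0.115) or Ercc1 library 1 (0.0880), with a stricter filter (0.0875) and with age as a covariate (0.0831).

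Hepatocyte markers were 10 lower and 0 higher of 16 in Ercc1 (14 lower over the list alone), with a median of -0.71 (adjusted p = 5.20e-07, but 0.0893 with an estimated correlation). Alpha-1 antitrypsin paralogs led the list: Serpina1c fell by 2.85 ± 0.22, Serpina1a fell by 2.28 ± 0.20 and Serpina1b fell by 1.42 ± 0.15. Genes of gluconeogenesis and amino acid catabolism were 14 lower and 0 higher of 27 (20 lower over the list alone), with a median of -0.88 (adjusted p = 6.63e-08, but 0.219 with an estimated correlation). The glucose-6-phosphate transporter gene Slc37a4 fell by 1.19 ± 0.18, serine dehydratase (Sds) fell by 2.21 ± 0.35 and Ppargc1a, a coactivator of the fasting response, fell by 1.504 ± 0.24. Fatty acid synthesis genes were 6 lower of 22 (7 over the list alone). Their median was -0.69 (adjusted p = 8.47e-04, but 0.466 with an estimated correlation and 0.0831 with age as a covariate, where the median was -0.14). Dgat2 fell by 1.58 ± 0.22 and Mlxipl, the carbohydrate-response transcription factor, fell by 1.096 ± 0.18. Circadian clock genes were 7 lower of 20 (9 over the list alone), with a median of -1.27 (adjusted p = 3.97e-04, but 0.192 with an estimated correlation), led by Bhlhe40 (-1.41 ± 0.18), Hlf (-1.46 ± 0.21) and Per1 (-2.49 ± 0.40). The labels give no collection times or feeding state, so an effect of either on this clock change cannot be told from the Ercc1 genotype. The same limit holds for the gluconeogenesis and fatty acid synthesis lists, though both were also lower in NemoDK_Ercc1 against WT. Cytochrome P450 and xenobiotic genes were 2 higher and 7 lower of 24 (3 and 9 over the list alone), with a median of -0.28 (adjusted p = 0.0302, but 0.466 with an estimated correlation). Ces2a fell by 1.82 ± 0.18 and Cyp2c29 fell by 1.88 ± 0.29. That call ended without WT library 2 (adjusted p = 0.0512), Ercc1 library 1 (0.0590) or Ercc1 library 2 (0.0576).

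**Figure D3:**
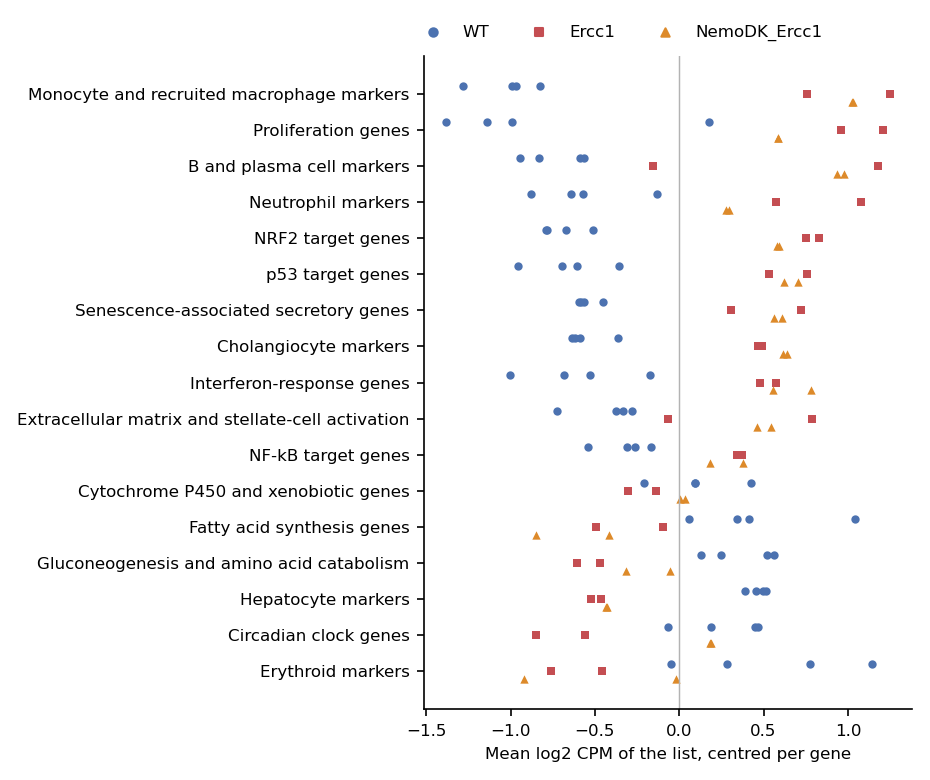
Mean log2 CPM of the 17 gene lists that passed in Ercc1 against WT (camera with a preset correlation), centred per gene, in each library (n = 4 WT, 2 Ercc1 and 2 NemoDK_Ercc1 mice). Lists are ordered by their mean change.

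The genes with the largest rises in Ercc1 were nearly silent in WT. Sprr1a and Tinag had 0 counts in the 4 WT libraries and 693 and 435 in the Ercc1 libraries, which put them at least 364-fold and 228-fold higher. Aqp7 had 1 WT count and was 296-fold higher (95% counting interval 52.5 to 11748), and Adam32 had 2 and was 195-fold higher (53.5 to 1620). They were followed by Lrtm2 (7.53 ± 0.63), Ly6d (7.31 ± 0.34), Dnah1 (7.16 ± 0.59), Hr (6.58 ± 0.35), Gsta1 and Nptx1 (6.37 ± 0.48). With all libraries the largest falls were in Mup11 (-7.38 ± 1.58), Mup13 (-7.31 ± 0.90), Mup1 (-7.24 ± 1.88), Mup12 (-6.98 ± 1.59), Mup16 (-6.74 ± 0.79), Serpina1e (-6.67 ± 1.51), Mup18 (-6.48 ± 0.62), Mup9 (-6.23 ± 0.78) and Serpina12 (-5.63 ± 0.51). Nat8f7, with 2 counts in Ercc1, was 108-fold lower (95% counting interval 29.6 to 893). Over all 22 major urinary protein genes, which encode pheromone carriers made in the liver under growth hormone control, the sum was 13613 ± 12324 CPM in WT (mean ± SD) and 1268 ± 561 in Ercc1. WT library 3 alone held 31898 CPM, and the other WT libraries averaged 7518 ± 2224. Mup20, chosen after its values were seen, went the other way: it was 13.3, 10.5 and 11.0 CPM in WT libraries 1, 2 and 4, 1024 in WT library 3, and 236 and 530 in Ercc1 (0.53 ± 1.69, adjusted p = 0.851, but 5.05 with adjusted p = 1.29e-04 without WT library 3). WT library 3 enlarged several of the falls in Mup genes and Serpina1e, which without it were -4.66 for Serpina1e, -4.97 for Mup1, -5.42 for Mup12, -6.07 for Mup11, -6.12 for Mup16 and -6.60 for Mup13. Without Ercc1 library 1 the calls ended for Mup11 (-6.55, adjusted p = 0.0899), Mup1 (-6.81, 0.166), Mup12 (-6.17, 0.115), Serpina1e (-6.56, 0.122) and Nat8f7 (0.141). Without Ercc1 library 2 they ended for Mup1 (-7.91, adjusted p = 0.129), Mup12 (-9.11, 0.0562), Serpina1e (-6.80, 0.0995) and Nat8f7 (0.0983). The paralogs are nearly identical, so single Mup values are less certain than the family sum.

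Other lists did not pass in Ercc1 against WT. Acute-phase genes were 6 higher and 6 lower of 31 (6 and 9 over the list alone; adjusted p = 0.519), DNA repair genes 6 and 1 of 42 (4 and 1; 0.421), bile acid genes 3 and 6 of 21 (4 and 7; 0.236), and unfolded-protein response genes 2 and 1 of 23 (2 and 1; 0.531). MHC class II genes were 1 and 0 of 12 (1 and 0; 0.184), cholesterol synthesis genes 0 and 1 of 25 (0 and 1; 0.181), growth hormone and IGF1 genes 0 and 2 of 10 (0 and 2; 0.165), and heat-shock genes 1 and 1 of 14 (1 and 1; 0.905). Nuclear oxidative phosphorylation genes were 0 and 2 of 32 (0 and 2; 0.0871), Kupffer cell markers 2 and 1 of 15 (2 and 1; 0.184), T and NK cell markers 0 and 0 of 17 (0 and 0; 0.263), and sinusoidal endothelial markers 1 and 2 of 16 (1 and 2; 0.531). Fatty acid oxidation genes were 5 higher and 1 lower of 30 (5 and 1 over the list alone), where the median was -0.07, the mean 0.29 and the test pointed higher (adjusted p = 0.181). Adipocyte markers were 0 and 0 of 3 (0 and 0), where the median was 0.23, the mean -0.26 and the test pointed lower (0.916). Male-biased liver genes were 0 higher and 1 lower of 17 (0 and 1 over the list alone; adjusted p = 0.318). Female-biased liver genes were 0 and 0 of 20 (0 and 0) with a median of -1.91 (adjusted p = 0.102). Some of these lists passed when a library was left out: fatty acid oxidation genes without WT library 4 (higher, 4.18e-04) or Ercc1 library 1 (higher, 0.0395), and Kupffer cell markers (8.53e-04), MHC class II genes (0.00267) and cholesterol synthesis genes (lower, 0.0340) without WT library 2. Without Ercc1 library 1 Kupffer cell markers (0.0136), MHC class II genes (0.0157), cholesterol synthesis genes (lower, 0.00281), oxidative phosphorylation genes (lower, 0.00199) and female-biased genes (lower, 0.0395) passed. Heat-shock genes (lower, 3.88e-07, median -1.39), female-biased genes (lower, 2.94e-05), oxidative phosphorylation genes (lower, 3.13e-04) and cholesterol synthesis genes (lower, 0.0198) passed with age as a covariate. None of these gains held with an estimated correlation. Without WT library 3, 18 of the 20 female-biased genes were lower in Ercc1, with a median of -2.30 (adjusted p = 5.73e-19, but 0.209 with an estimated correlation).

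Livers of NemoDK_Ercc1 mice stood close to those of Ercc1 mice, which were older, so the Nemo allele and age cannot be separated in this comparison. Lists of p53 targets, secretory genes, interferon-response genes and macrophage markers did not pass between the mutant groups, which does not show that their levels were equal. Lists that passed in every leave-out were circadian clock genes, whose Per and Dbp arm was higher and Arntl arm lower in NemoDK_Ercc1, and unfolded-protein response genes, which were lower. Neither passed with an estimated correlation (adjusted p = 0.315 and 0.699), and with fry 0 of 34 lists passed. Over the alternatives the median ranged from 0.75 to 1.28 for clock genes and from -0.66 to -0.19 for unfolded-protein response genes. No single gene passed in edgeR between NemoDK_Ercc1 and Ercc1: 0 were higher and 0 lower (smallest adjusted p = 0.539). At unadjusted p under 0.05 there were 513 higher and 549 lower genes, against 780 in all expected by chance. DESeq2 called 33 higher and 36 lower, limma-voom 0 and 0, and edgeR without the filter on low counts 28 and 37. In data simulated with the same spread, 200 changed genes and a shifted NF-kB list, this contrast recovered mainly large changes. Of 2-fold changes 27.4% passed, and of 4-fold changes 86.7%.

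NF-kB targets, the genes nearest to the Nemo allele, were 0 higher and 0 lower of 40 (0 and 2 over the list alone), with a median of -0.08 in NemoDK_Ercc1 against Ercc1 (adjusted p = 0.0912, and 0.9495 with an estimated correlation). The list passed without NemoDK_Ercc1 library 1 (lower, adjusted p = 0.0329, but 0.730 with an estimated correlation). Its 4 members with the smallest p were Tnfaip2, a TNF-induced gene (-1.27 ± 0.18, from 59.2 to 24.5 CPM), Bcl3, a nuclear IkB protein gene (-1.15 ± 0.24), Tnfaip3, the A20 feedback inhibitor gene (-0.68 ± 0.23), and Nfkbia, the IkB-alpha gene, which moved the other way (0.35 ± 0.13). Their edgeR adjusted p values were 0.539, 0.539, 0.653 and 0.683. DESeq2 called Tnfaip2 (adjusted p = 1.91e-05) and Bcl3 (0.0119). In WT, Tnfaip2 stood at 38.6, 29.6, 29.7 and 30.4 CPM, between the mutant groups. Cdkn1a was 104 and 66.2 CPM in Ercc1 and 45.4 and 40.5 in NemoDK_Ercc1 (-0.99 ± 0.79, adjusted p = 0.849).

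Circadian clock genes were 0 higher and 0 lower of 20 over all genes but 9 higher and 3 lower over the list alone, with a median of 0.97 (camera, adjusted p = 2.25e-06, but 0.315 with an estimated correlation). Per1 was 43.6, 88.3, 39.1 and 44.3 CPM in WT, 10.8 and 8.28 in Ercc1, and 53.5 and 90.3 in NemoDK_Ercc1 (2.91 ± 0.44, edgeR adjusted p = 0.539, DESeq2 7.47e-09). Ciart rose by 3.96 ± 0.91 (edgeR adjusted p = 0.588, DESeq2 0.0263) and Bhlhe40 by 1.08 ± 0.19 (0.539 and 9.75e-04), while Nfil3 fell by 1.61 ± 0.39 (0.588 and 0.0170). Tef, chosen after its values were seen, rose by 1.86 ± 0.58 (0.648 and 0.0492). Genes of gluconeogenesis and amino acid catabolism were higher as a list (2 and 1 over the list alone; median 0.27, adjusted p = 0.00154, but 0.9495 with an estimated correlation, 0.209 with age as a covariate and 0.0716 without NemoDK_Ercc1 library 2). Ppargc1a rose by 1.21 ± 0.26 (edgeR adjusted p = 0.588, DESeq2 0.0201).

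**Figure D4:**
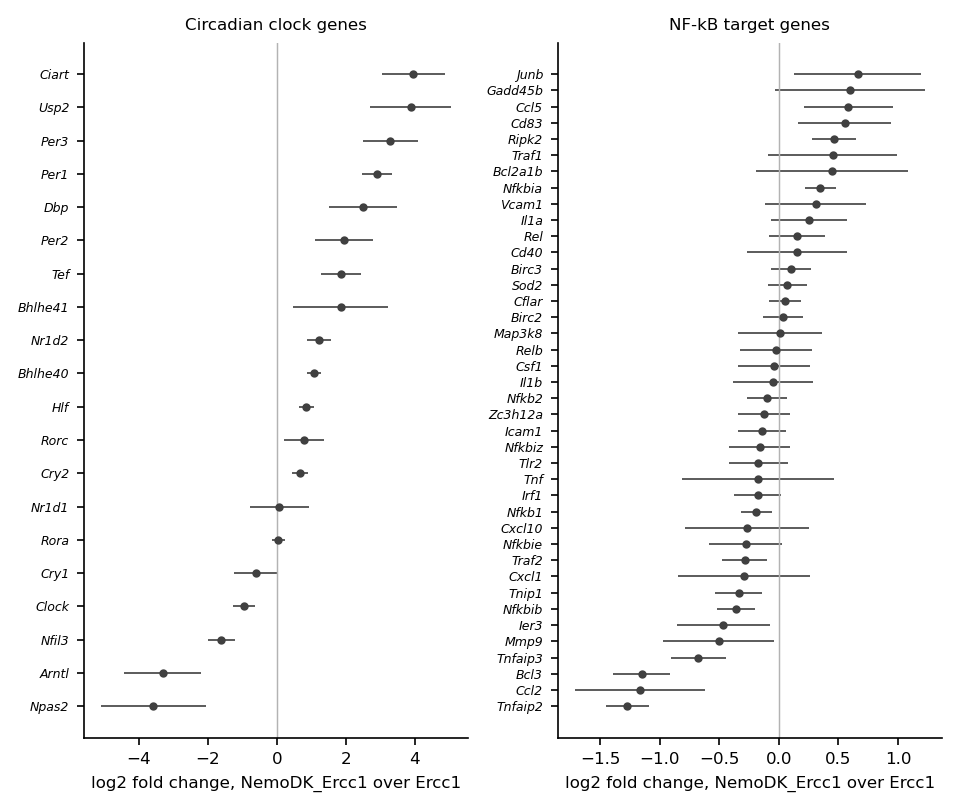
Log2 fold change ± standard error of circadian clock genes and NF-kB targets in NemoDK_Ercc1 over Ercc1 (n = 2 mice each). No gene shown had an edgeR adjusted p under 0.05.

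T and NK cell markers were also higher as a list in NemoDK_Ercc1 (median 0.55, adjusted p = 0.0101, but 0.9495 with an estimated correlation). Of the lists that were lower, unfolded-protein response genes had a median of -0.45 (adjusted p = 4.33e-05, but 0.699 with an estimated correlation), with the chaperone genes Hyou1 (-1.28 ± 0.37, edgeR adjusted p = 0.637) and Manf (-1.31 ± 0.40, 0.648) lower and Herpud1 higher (1.19 ± 0.29, 0.588). DESeq2 called only Herpud1 of this list (adjusted p = 0.0201, against 0.0710 for Hyou1 and 0.0922 for Manf), the member that went against the direction of the list. Hyou1 and Manf were 233 and 117 CPM in Ercc1 library 1. In Ercc1 library 2 they were 116 and 54.7 CPM, within the WT ranges of 98.0 to 188 and 36.6 to 71.6. Proliferation genes had a median of -0.51 (adjusted p = 4.33e-05, but 0.9495 with an estimated correlation), cholesterol synthesis genes -0.50 (4.52e-04, but 0.9495), NRF2 targets -0.17 (0.0101, but 0.699), neutrophil markers -0.45 (0.0101, but 0.699) and fatty acid synthesis genes -0.32 (0.0197, but 0.9495). In each of these 7 lists 0 genes passed in edgeR, over all genes and over the list alone. Besides Herpud1, DESeq2 called the NRF2 target Gclc (-0.90, adjusted p = 0.0362), chosen after its values were seen. Fewer of them passed without Ercc1 library 1: proliferation genes had an adjusted p of 0.0617, NRF2 targets 0.0878, fatty acid synthesis genes 0.314, cholesterol synthesis genes 0.630, neutrophil markers 0.202 and T and NK cell markers 0.340. Without NemoDK_Ercc1 library 1 fatty acid synthesis genes (0.692), cholesterol synthesis genes (0.2199) and T and NK cell markers (0.0934) did not pass. With age as a covariate proliferation genes (now higher, 0.173), cholesterol synthesis genes (now higher, 0.936), neutrophil markers (0.147) and T and NK cell markers (0.733) did not pass.

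Other lists did not pass between the mutant groups, and in none of them did a gene pass over all genes in edgeR. The p53 targets had a median of 0.07 (1 higher over the list alone; adjusted p = 0.910), secretory genes 0.06 (0.355), interferon-response genes 0.15 (1 higher over the list alone; 0.218) and extracellular matrix genes 0.08 (0.355). Usp18 was 0.78 ± 0.16 higher in NemoDK_Ercc1 (edgeR adjusted p = 0.539, DESeq2 0.0335), and so was the p53 target Plk3 (1.30 ± 0.26, 0.539 and 0.00399). DESeq2 also called the fatty acid oxidation gene Pdk4 (-2.54, 4.13e-04) and the bile acid gene Hsd3b7 (-0.99, 0.0175), both chosen after their values were seen. Acute-phase genes had a median of -0.11 (0.180), MHC class II genes 0.23 (0.328), DNA repair genes -0.06 (0.589), growth hormone and IGF1 genes 0.11 (1 lower over the list alone; 0.910), cytochrome P450 genes 0.13 (0.142) and bile acid genes -0.09 (1 lower over the list alone; 0.355). Heat-shock genes had a median of -0.08 (0.142), nuclear oxidative phosphorylation genes -0.04 (0.285), hepatocyte markers 0.07 (0.910), Kupffer cell markers 0.28 (0.0909), B and plasma cell markers 0.34 (0.0545), sinusoidal endothelial markers 0.07 (0.355), cholangiocyte markers 0.28 (0.589) and erythroid markers 0.20 (0.515). Female-biased liver genes had a median of 0.58 (0.285) and male-biased genes -0.37 (0.155). Median, mean and test differed in sign for cyclin-dependent kinase inhibitors (0.08, -0.21, lower, 0.910), fatty acid oxidation genes (-0.03, 0.06, lower, 1 lower over the list alone, 0.910), monocyte markers (0.14, 0.01, lower, 1 lower over the list alone, 0.910) and adipocyte markers (0.00, -0.02, lower, 0.910). With WT library 3 left out, female-biased genes (higher, 0.00322), male-biased genes (lower, 7.14e-04), cytochrome P450 genes (higher, 0.0250) and B and plasma cell markers (higher, 0.0457) passed, but none did with an estimated correlation (0.778 for the first 3 and 0.788 for the last). Without Ercc1 library 2, B and plasma cell markers (3.66e-07), extracellular matrix genes (3.66e-07), Kupffer cell markers (0.00487), secretory genes (0.0179) and MHC class II genes (0.0203) passed as higher, and heat-shock genes (0.0203) and oxidative phosphorylation genes (0.00609) as lower. Interferon-response genes passed as higher without NemoDK_Ercc1 library 2 (0.0105), and erythroid markers without NemoDK_Ercc1 library 1 (0.00884). Interferon-response genes (0.0464) and Kupffer cell markers (0.0201) passed as higher without WT library 2, male-biased genes as lower without NemoDK_Ercc1 library 1 (0.0404), and B and plasma cell markers as higher without WT library 1 (0.0480), 2 (0.0464) or 4 (0.0455). With an estimated correlation none of these leave-out gains held (smallest adjusted p = 0.129). B and plasma cell markers also passed as higher with RLE factors (0.0388) and with a filter at 1 CPM in 2 libraries (0.0176). Neither of these 2 gains held with an estimated correlation (0.930 and 0.926). With age as a covariate interferon-response genes were higher (median 0.86, adjusted p = 1.14e-10) and monocyte markers lower (-1.13, 0.0318), but neither list passed with an estimated correlation (0.678 for both). Age as a covariate also turned some directions around: extracellular matrix genes (7.75e-07) and B and plasma cell markers (0.0142) passed as lower, and heat-shock genes (2.24e-06) and oxidative phosphorylation genes (0.0409) as higher. Extracellular matrix genes were lower without Ercc1 library 1 too (6.02e-04). Female-biased genes (higher, 3.93e-05), male-biased genes (lower, 0.00114) and cytochrome P450 genes (higher, 0.0335) passed with age as well, and none of these did with an estimated correlation.

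Livers of NemoDK_Ercc1 mice, which were as young as the WT mice, also had higher p53 and NRF2 target, interferon-response and macrophage genes and lower hepatocyte genes than WT. Fatty acid and cholesterol synthesis genes were lower, and proliferation genes and markers of B and plasma cells and of T and NK cells were higher. Of 18 lists that passed with a preset correlation, 0 passed with an estimated one. With fry 17 of 34 lists passed. Against WT, 1646 genes were higher and 1154 lower (edgeR), 1115 and 367 of them at least 2-fold. Without TMM factors the counts were 3508 and 490 with a median log2 change of 0.27 over all tested genes, and with upper-quartile factors 2048 and 783 with a median of 0.10. With age as a covariate they were 1584 and 1058, of which 2388 were among the 2800 genes called without it (85.3% of these) and 254 were new. Without NemoDK_Ercc1 library 1 the counts were 380 and 157, and without NemoDK_Ercc1 library 2 they were 451 and 172.

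In NemoDK_Ercc1 livers p53 targets were 18 higher and 0 lower of 34 (21 and 0 over the list alone), with a median of 0.83 (adjusted p = 1.35e-13, but 0.128 with an estimated correlation). Phlda3 rose by 4.19 ± 0.27, the cyclin G1 gene Ccng1 by 1.23 ± 0.13, the pro-apoptotic gene Bax by 0.94 ± 0.10 and Cdkn1a by 3.65 ± 0.70 (adjusted p = 0.0104). The Cdkn1a call ended without NemoDK_Ercc1 library 1 (3.56, adjusted p = 0.0667) or library 2 (3.73, 0.0550). NRF2 targets were 13 and 0 of 26 (15 and 0), with a median of 0.83 (1.01e-11, but 0.0553 with an estimated correlation), with Gsta2 up by 3.42 ± 0.29 and Ugdh by 1.71 ± 0.14. Interferon-response genes were 26 and 0 of 41 (31 and 0), with a median of 1.18 (4.20e-21, but 0.241), with Usp18 up by 3.06 ± 0.14, Ifi44 by 3.06 ± 0.31 and Oas1g by 2.97 ± 0.31. Secretory genes were 18 and 1 of 41 (21 and 2), with a median of 0.79 (2.35e-07, but 0.128). Mmp12 rose by 6.11 ± 0.46 and Plaur by 2.40 ± 0.31, and Lif, with 96 counts, was 79.3-fold higher (95% counting interval 21.4 to 665). NF-kB targets were 12 and 2 of 40 (12 and 3), with a median of 0.51 (0.0125, but 0.460, and 0.0580 without NemoDK_Ercc1 library 1), with Cd83 up by 2.63 ± 0.35, Tlr2 by 1.61 ± 0.22 and Cd40 by 2.68 ± 0.41. Proliferation genes were 7 and 0 of 38 (12 and 0), with a median of 1.39 (1.12e-06, but 0.474), E2f1 rising by 1.99 ± 0.21.

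Monocyte and recruited macrophage markers were 9 higher and 0 lower of 13 in NemoDK_Ercc1 against WT (11 and 0 over the list alone), with a median of 1.33 (adjusted p = 1.58e-10, but 0.128 with an estimated correlation). Gpnmb rose by 5.62 ± 0.58, Trem2 by 3.03 ± 0.43 and Itgax by 2.53 ± 0.32. B and plasma cell markers were 12 and 0 of 17 (15 and 0), with a median of 1.77 (6.34e-07, but 0.384), T and NK cell markers 5 and 0 of 17 (6 and 0), with a median of 0.89 (0.00884, but 0.497), and Kupffer cell markers 3 and 1 of 15 (4 and 1), with a median of 0.76 (0.0129, but 0.612, and 0.0501 without WT library 4). MHC class II genes were 1 and 0 of 12 (1 and 0), with a median of 0.50 (0.0438, but 0.612), led by the lysosomal thiol reductase gene Ifi30 (1.24 ± 0.18). That call ended without WT library 1 (adjusted p = 0.0608), WT library 3 (0.0637), WT library 4 (0.135) or NemoDK_Ercc1 library 1 (0.0607). Extracellular matrix genes were 12 and 1 of 29 (16 and 1), with a median of 0.83 (1.19e-06, but 0.466), with Col1a1 up by 2.75 ± 0.37 and Vim by 1.41 ± 0.21. Cholangiocyte markers were 4 and 0 of 10 (7 and 1), with a median of 1.12 (0.00391, but 0.128), with Krt23 up by 3.72 ± 0.44 and the osteopontin gene Spp1 by 0.98 ± 0.13.

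Hepatocyte markers were 0 higher and 9 lower of 16 in NemoDK_Ercc1 against WT (0 and 13 over the list alone), with a median of -0.67 (adjusted p = 3.06e-07, but 0.0885 with an estimated correlation). Serpina1c fell by 2.91 ± 0.22 and Serpina1a fell by 2.19 ± 0.20. Fatty acid synthesis genes were 0 and 8 of 22 (0 and 15), with a median of -0.96 (1.19e-06, but 0.384), Mlxipl falling to 221 CPM from 594 (-1.43 ± 0.19). Cholesterol synthesis genes were 0 and 5 of 25 (0 and 8), with a median of -0.61 (7.48e-04, but 0.557). Genes of gluconeogenesis and amino acid catabolism were 0 and 7 of 27 (0 and 7), with a median of -0.48 (1.43e-04, but 0.460). Nuclear oxidative phosphorylation genes were 0 and 3 of 32 (0 and 2), with a median of -0.21 (0.0116, but 0.686).

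Of the 10 largest rises in NemoDK_Ercc1, 7 were also among the 10 largest in Ercc1, measured against the same nearly silent WT libraries. Sprr1a was at least 245-fold and Tinag at least 190-fold higher than the floor set by 0 WT counts, Aqp7 was 387-fold higher (95% counting interval 68.7 to 15342) and Adam32 176-fold higher (48.1 to 1463). Lrtm2 (7.94 ± 0.63), Dnah1 (6.67 ± 0.60), Gsta1 (6.25 ± 0.28), Psrc1 (6.12 ± 0.41), the ubiquitin-like gene Ubd (6.46 ± 0.41) and the monoacylglycerol acyltransferase gene Mogat2 (6.14 ± 0.38) completed the set. Among the largest falls Mup13, with 3 counts in NemoDK_Ercc1, was 2055-fold lower (703 to 9969), and Nat8f7, with 0 counts, at least 68.4-fold lower. The others were Mup1 (-9.45 ± 2.26), Mup15 (-9.33 ± 2.0001), Mup11 (-8.92 ± 1.72), Mup12 (-8.81 ± 1.78), Mup9 (-8.45 ± 0.86), Mup18 (-8.12 ± 0.68), Mup17 (-8.10 ± 0.78) and Mup16 (-7.43 ± 0.83), and the family sum was 743 ± 355 CPM. Without WT library 3 the falls were -7.19 in Mup1, -7.26 in Mup12, -7.64 in Mup11 and -8.91 in Mup15. Without NemoDK_Ercc1 library 1 calls ended for Nat8f7 (adjusted p = 0.124), Mup1 (-10.73, 0.155), Mup15 (-9.59, 0.128), Mup11 (-8.9996, 0.102) and Mup12 (-10.98, 0.0846). Without NemoDK_Ercc1 library 2 they ended for Nat8f7 (0.107), Mup1 (-8.90, 0.158), Mup15 (-9.13, 0.130), Mup11 (-8.86, 0.0994) and Mup12 (-8.07, 0.109).

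The lists that did not pass in NemoDK_Ercc1 against WT were cyclin-dependent kinase inhibitors (1 higher and 0 lower of 6, 2 and 0 over the list alone, adjusted p = 0.229, but 0.00445 without WT library 1, and 0.184 there with an estimated correlation), acute-phase genes (6 and 8 of 31, 6 and 12, 0.136), growth hormone and IGF1 genes (1 and 1 of 10, 1 and 4, 0.136), female-biased genes (0 and 1 of 20, 0 and 1, 0.229), male-biased genes (0 and 2 of 17, 0 and 1, 0.0885) and cytochrome P450 genes (2 and 4 of 24, 2 and 6, 0.136). Bile acid genes were 1 and 7 of 21 (2 and 7, 0.0683), circadian clock genes 0 and 2 of 20 (0 and 0, 0.2198), unfolded-protein response genes 1 and 5 of 23 (2 and 6, 0.113), heat-shock genes 1 and 1 of 14 (1 and 1, 0.264), fatty acid oxidation genes 4 and 1 of 30 (4 and 1, 0.155), neutrophil markers 1 and 0 of 6 (2 and 0, 0.0683) and erythroid markers 0 and 0 of 7 (1 and 5, 0.0650). Median, mean and test differed in sign for DNA repair genes (4 and 1 of 42, 2 and 0, median -0.02, mean 0.21, higher, 0.601), sinusoidal endothelial markers (1 and 1 of 16, 1 and 1, median -0.10, mean 0.06, lower, 0.920) and adipocyte markers (0 and 0 of 3, 0 and 1, median 0.23, mean -0.27, lower, 0.903). Without WT library 3, 12 of the 20 female-biased genes were lower (adjusted p = 4.70e-14, but 0.207 with an estimated correlation). Acute-phase genes (lower, 0.0137), cytochrome P450 genes (lower, 0.0420), bile acid genes (lower, 0.0246) and erythroid markers (lower, 0.0420) also passed there. Other gains were fatty acid oxidation genes (higher, 2.91e-04) and erythroid markers (lower, 0.0163) without WT library 4, erythroid markers without NemoDK_Ercc1 library 2 (lower, 3.69e-04), bile acid genes without WT library 2 (lower, 0.0476) or NemoDK_Ercc1 library 1 (lower, 0.0393), and unfolded-protein response genes without WT library 2 (lower, 0.0464). Male-biased genes passed as lower without WT library 1 (0.0213), WT library 2 (0.0343), WT library 4 (0.0324) or NemoDK_Ercc1 library 1 (0.0346), neutrophil markers as higher without WT library 1 (0.0298), and heat-shock genes as lower with age as a covariate (0.0332). None of these gains held with an estimated correlation.

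Both mutant groups were set against the same WT libraries, so shared calls were judged with the controls split. In the full fit 1205 genes were higher and 819 lower in both comparisons, where 186 and 110 would be shared by independent lists, and 0 went opposite ways. When the 4 WT mice were divided 2 and 2 between the comparisons, in 6 ways, 606 to 657 genes were higher and 425 to 486 lower in both, against 57.6 to 88.9 and 35.6 to 57.0 for independent lists. In 20 simulations of unchanged groups set beside the real WT libraries no gene was called in either comparison. The 3243 and 2800 genes with the smallest p were therefore taken in each simulation, a step chosen after the data were seen. Of these, 325 to 366 were shared in the same direction (mean 342), where independent lists would share 310 and the real comparisons shared 2024. Another 308 to 375 were shared in opposite directions. The simulated groups were drawn around the mean of the same WT libraries, which removes the error that shared controls add to both comparisons. They therefore cannot show how many calls shared controls alone would produce.

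How much of the Ercc1 change was found in NemoDK_Ercc1 mice was measured on libraries not used for choosing the genes. The Ercc1 mice were older, so this share cannot separate the Nemo allele from age. The 100 genes with the largest rise in 1 Ercc1 mouse over 2 WT mice had a median log2 change of 3.52 in the other Ercc1 mouse against the other 2 WT mice (3.21 to 3.995 over 12 choices of mice), and of 3.51 in NemoDK_Ercc1 (2.87 to 4.02 over mice). This was 99.6% of the Ercc1 level, a difference of -0.01 (-0.42 to 0.19 over the 12 choices). The choices reuse the same mice, so their range does not measure the spread between mice. With these rises chosen in Ercc1 mouse 1 the medians were 3.36 in the other Ercc1 mouse and 3.23 in NemoDK_Ercc1. With mouse 2 used for choosing they were 3.69 and 3.79. For the 100 genes with the largest fall the medians were -2.76 in Ercc1 (-3.23 to -2.30) and -2.56 in NemoDK_Ercc1 (-3.01 to -1.76), or 92.9%, a difference of 0.20 (-0.10 to 0.45). The answer for the falls turned with the number of genes taken: it was 113% for the top 50 (a difference of -0.49, -0.75 to -0.13) and 78.6% for the top 200 (0.39, 0.10 to 0.60). For the rises it was 103% for the top 50 (0.12, -0.20 to 0.44) and 91.5% for the top 200 (-0.27, -0.44 to -0.12).

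In counts simulated with the spread and depth of these libraries, the Ercc1 comparison recovered 4.82% of 1.5-fold, 37.9% of 2-fold, 88.8% of 4-fold and 97.2% of 8-fold changes, with 6.45% of calls false. The comparison between the mutant groups recovered 1.6%, 27.4%, 86.7% and 95.2%, with 5.5% false. These rates hold for the simulated 200 changed genes above 1 CPM plus the shifted NF-kB list. With another number of changed genes the recovery would differ.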

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

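All tests of WT library 3 itself were chosen only after the result was seen. So were, for monocyte markers, the tests of the hepatocyte share and of the age of NemoDK_Ercc1 mice. The tests of clock genes and of the effect of WT library 3 on monocyte markers were written before they were run. The limit for the age test of clock genes equals their observed mean change without age, however, so it was set after that change was seen. A WT library was called far from the other 3 when its gap to the nearest, divided by the range of the group, passed the Dixon limit, which chance passes in about 1 of 20 groups. Of 96 genes 11 passed, 6 of them in WT library 3. That library was highest for Aqp7 (ratio 1, from a single count), Dnah1 (0.876), Serpina1e (0.934), Mup20 (0.949) and Rian (0.867) and lowest for Cd83 (0.973). WT library 1 was highest for Adam32 (1, from few counts), Tnfaip2 (0.904) and Ccng1 (0.846) and lowest for Mup15 (0.874), and WT library 2 was highest for Per1 (0.847). Of 34 lists 3 passed: fatty acid oxidation and PPAR-alpha targets in WT library 4 (highest, 0.831), and female-biased (lowest, 0.980) and male-biased liver genes (highest, 0.928) in WT library 3. Of 15 measures of the libraries 5 passed, all in WT library 3: the sum of Y-linked counts and each of Ddx3y, Eif2s3y, Kdm5d and Uty (ratio 1 each). Y-linked genes, which no comparison used, had 3087 counts in WT library 3, 10 in Ercc1 library 2 and 0 in the other libraries.

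WT library 3 was labelled female but had no Xist counts and many Y-linked counts. Low depth did not explain it, with 24.6 M counts against 22.2 to 27.8 M in the other WT libraries, nor did male RNA mixed into a female sample, since 0 Xist counts allow at most 0.0280% of the level of the other WT libraries. A male mouse with a wrong label fitted: all 17 autosomal male-biased genes lay above and all 20 female-biased genes below every other WT library, a median difference of 14.8 log2 units between the lists. Whether the label of sex or the whole sample was exchanged was not tested.

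Clock genes differed as a list between NemoDK_Ercc1 and Ercc1 livers with a preset correlation (adjusted p = 2.25e-06), but not with an estimated one (0.315), and no clock gene passed in edgeR. The list holds arms that peak at opposite times of day. The median change of the Per and Dbp arm (9 of 9 higher, 1.95) minus that of the Arntl arm (1 of 6 higher, -1.28) was 3.23, so a different time of day or feeding at collection fitted. An effect of the older age of the Ercc1 mice could not be told from the groups: with age as a covariate the mean change was 0.81, against 0.84 without, but no Ercc1 mouse was as young as any NemoDK_Ercc1 mouse. An effect of the Nemo allele on the clock stays open and untested, as the labels give no collection times.

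Markers of monocytes and recruited macrophages were higher in Ercc1 than in WT (adjusted p = 1.13e-10, but 0.192 with an estimated correlation). A lower share of hepatocytes, which would raise markers of every other cell type alike, did not explain the whole rise. The mean change of monocyte markers exceeded that of sinusoidal endothelial markers (-0.03) by 2.14. The lowest Ercc1 library (0.76) lay above the highest WT library (-0.82) for monocyte markers. Other mean changes were 0.43 (T and NK cell), 0.45 (Kupffer cell), 1.11 (cholangiocyte), 1.49 (neutrophil) and 1.501 (B and plasma cell markers). Adipocyte (-0.26) and erythroid markers (-1.53) were lower. A partial contribution of a lower hepatocyte share therefore stays open, and the fall of hepatocyte markers was not tested here. The male-like WT library 3 did not explain the monocyte rise, as 104% of the monocyte change was kept without it. Nor did age alone, since NemoDK_Ercc1 mice, within the age range of WT, had 100.4% of the change. A biological difference, more or more active macrophages in ERCC1-deficient liver, stays a hypothesis, and numbers of cells were not measured.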

How the results depend on the processing

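Leaving out WT library 3 together with age, DESeq2 or an estimated correlation was chosen after seeing the data; the other alternatives were fixed earlier. Where the only change was RLE or upper-quartile factors, a stricter filter, limma-voom or robust empirical Bayes, the numbers of called genes stayed within 1.5 times the main ones. Even so limma-voom and robust empirical Bayes ended calls of 2 and 4 of 70 named genes in Ercc1 against WT and of 5 and 3 of 51 in NemoDK_Ercc1 against WT, all of them Mup genes, Serpina1e or Nat8f7. In Ercc1 against WT, library size alone gave 3765 higher and 690 lower genes, a fold threshold of 2 gave 1122 and 533, and an adjusted p under 0.10 gave 2299 lower. Age as a covariate gave 24 and 17, and with WT library 3 also left out 108 and 78 (38 and 144 of these calls were also made with all libraries and no age), because age and the Ercc1 group are nearly confounded. Of the 70 named genes 62 lost the call with age. In NemoDK_Ercc1 against Ercc1, where edgeR called 0 and 0, no filter gave 28 and 37, DESeq2 33 and 36, DESeq2 without WT library 3 gave 62 and 80, and a fit of only the 2 groups 1 higher. In NemoDK_Ercc1 against WT, library size alone gave 3508 and 490, the fold threshold 367 lower and an adjusted p under 0.10 1891 lower. The cause was not tested, apart from age.

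Lists passing fell from 17, 9 and 18 in the 3 comparisons to 1, 0 and 0 with an estimated correlation, to 0, 0 and 0 when WT library 3 was also left out, and to 13, 0 and 17 with fry. The change of Ercc1 transcript between the mutant groups reversed to -0.33 with age and to -0.43 with age and without WT library 3, both far from the threshold. That of Mup20 in Ercc1 against WT, 0.53 in all libraries, was -0.17 without Ercc1 library 2, 5.05 without WT library 3 and 9.57 with age as a covariate. The share of the held-out rise kept in NemoDK_Ercc1 was 91.5% for 200 genes, and that of the fall 113% for 50 genes and 78.6% for 200. Shared calls averaged 638.5 higher and 460.8 lower with WT mice split, and 1377 were lower at adjusted p under 0.10.

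With each library left out in turn, Ercc1 against WT had 774 to 1845 higher and 383 to 1563 lower genes, NemoDK_Ercc1 against Ercc1 had 0 to 2 higher and 4 to 16 lists passing, and NemoDK_Ercc1 against WT had 380 to 1672 higher and 157 to 1344 lower. Where 1 mouse remained in a group, it is assumed to vary like the other groups. No paired analysis was possible because each library came from a different mouse. With 2 mice per mutant group, 2-fold changes were recovered in 37.9% and 27.4% of simulated cases.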

Other observations

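Both mutant groups had higher Meg3, Rian and Afp than WT. Meg3 and Rian, noncoding RNAs of 1 imprinted locus, rose by 4.28 ± 0.68 and 4.35 ± 0.42 in Ercc1 against WT and by 5.35 ± 0.69 and 5.0003 ± 0.42 in NemoDK_Ercc1 against WT. The alpha-fetoprotein gene Afp rose by 3.60 ± 0.48 and 4.14 ± 0.48. These 3 genes were chosen after their values were seen. Meg3 stood at 0.823, 0.957, 7.03 and 1.47 CPM in WT, 51.5 and 49.3 in Ercc1, and 125 and 86.0 in NemoDK_Ercc1. Without WT library 3 the changes of Meg3, Rian and Afp were 5.53, 5.04 and 4.35 in Ercc1 and 6.57, 5.66 and 4.87 in NemoDK_Ercc1, and with age as a covariate none of the 3 was called in Ercc1 against WT (5.59, 4.38 and 5.04, adjusted p = 0.238, 0.167 and 0.149), where the changes stayed as large and the errors grew, while all 3 were in NemoDK_Ercc1 against WT.

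Female-biased liver genes scored lower in both mutant groups than in the WT livers with a female pattern, without passing in either comparison at an estimated correlation (0.209 and 0.207). The mean score of the list was 2.32, 2.48 and 2.30 in WT libraries 1, 2 and 4, -6.67 in WT library 3, 0.01 and -0.86 in Ercc1, and -0.15 and 0.56 in NemoDK_Ercc1. Male-biased genes went both ways without WT library 3, with 6 higher and 4 lower of 17 in Ercc1 against WT (median 0.40, adjusted p = 0.855). Their score was -0.89, -0.69 and -0.55 in WT libraries 1, 2 and 4, 3.73 in WT library 3, -0.61 and 0.22 in Ercc1, and -0.24 and -0.98 in NemoDK_Ercc1.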
